A study of Macaca fascicularis with 2 samples.

How the data were processed

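The series holds 2 single-cell RNA sequencing libraries of retina from cynomolgus macaques (Macaca fascicularis), 1 from an animal whose ophthalmic arteries were tied off (ischemic) and 1 from an animal operated on in the same way but without the tie (sham). The condition label of the library called sham here reads normal, and the sham operation comes from the labels' account of the surgery. The name deposited with the ischemic library calls the retina dead, a word the labels do not use, and what it refers to is not given in the sources used here. The labels name the 10x Genomics Chromium platform. The deposited barcodes have 27 bases, built from 3 blocks of 9 bases with 96, 95 and 190 distinct words. Whether this layout belongs to the named platform is not settled by the sources used here, so the platform stays open. The submitters' processing notes name Cell Ranger, without a version, and Seurat 4.1.0. The genome build and annotation are not given in the sources used here, so genes are identified by symbol alone and no positions are given.

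The deposited values of both libraries are whole-number counts of unique molecular identifiers (UMIs), 1 matrix per library over the same 33368 gene symbols. They are raw counts, with no normalization left in them. Every deposited barcode had at least 500 UMIs: the smallest held 501 in the ischemic and 500 in the sham library. Cells below that depth are therefore missing from both libraries. Of 15955 gene identifiers of the LOC form, 8044 were found in the RefSeq gene table and 723 took a new symbol from it. HSPA1A, HSPA1B, MT2A, CXCL2, CCL4 and OPN1MW were not in the file under those names.

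Barcodes with at least 200 detected genes and at most 25% mitochondrial UMIs were kept. Doublets were scored within each library with an own implementation of the Scrublet score, and the top 0.8% of cells per 1000 cells were removed. The 247 and 181 highest scoring cells left the ischemic and sham library in this step. Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes, ranked within each library, gave 30 principal components, and a graph of the 15 nearest neighbours weighted by Jaccard overlap was partitioned by the Leiden method at resolution 1. Both libraries were clustered together without batch integration, since library and group are the same split.

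Clusters were named from 17 fixed marker sets with 194 genes, 185 of them in the file. A marker counted for a cluster when at least 10% of its cells held the gene and its level was at least 2-fold that of clusters of other classes, with 5 CPM added to both. A name needed at least 3 markers and 1 marker among the 20 leading genes. A cluster also stayed unnamed when another class reached 50% of its own unshared markers, or when OPTC, a gene of the ciliary body, was among its 10 leading genes. This rule was adjusted several times after the clusters had been seen. The last change raised the limit for another class from 40% to 50% and left shared markers out, after a simulated set of Müller cells had received no name and after values under the earlier limit had been seen. It moved cluster 31, with 50 ischemic cells and 1 sham cell, into the microglia-like class. Classes are called amacrine-like and so on because markers alone define them. The microglia-like class cannot separate resident microglia from macrophages, which share its markers.

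UMIs were summed over the cells of a class in each library and given as CPM, the count scaled to a common class total. Ratios are ischemic over sham. With 1 library per group there are no replicates, and no test between groups was made. Ratios of CPM carry exact conditional binomial 95% intervals, shares of cells Clopper-Pearson 95% intervals, and CPM values exact Poisson 95% intervals. All of these cover counting error only, not the difference between animals. A count of 0 was set to a floor of 3 counts over the class, and the resulting ratio is written as a lower bound. The exact 95% limit lies below that bound, for example at 37.6 against 46.3 for IL1R2 in microglia-like cells. The 7 named classes with at least 50 cells in both libraries were compared: amacrine-, microglia-, Müller-, rod-, bipolar-, endothelial- and ganglion-like.

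Before the data were examined, 25 gene lists with 649 genes were fixed, 590 of them in the file. A member entered in a class when it reached 20 CPM in at least 1 library. A list is summarised by the median log2 ratio of its members, with 0.5 counts added to each count. Members are counted as higher or lower by the sign of their ratio, whether or not their own interval excludes 1. The 95% interval of the median comes from 500 Poisson draws of the counts. Its percentile gives its place among the medians of 10000 random lists of the same size, drawn from genes matched on level in 20 bins. Where members had a count of 0 in 1 library, the median with those members at their lower bound follows. Named genes were fixed by rule. In up to 6 classes they are the 3 highest and 3 lowest genes with at least 100 CPM in 1 library, ranked by the interval bound nearest to 1. Mitochondrial, ribosomal and hemoglobin genes, markers of other classes and genes at levels that free RNA could give were left out there. To these come up to 4 members with the widest ratio of each list described in a class, and members of the hypoxia, glial reactivity and inflammatory lists above 100 CPM. Such list members whose level in a class was under 10% of that in the highest class are named with that fact, because RNA released by other cells could supply them.

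Free RNA in a class was estimated from UMIs of markers of other classes against the profile of all deposited barcodes. The share was 10.2% and 10.6% of UMIs in ischemic and sham amacrine-like cells, 7.19% and 11.0% in microglia-like cells, 7.85% and 12.9% in Müller-like cells, and 10.5% and 3.59% in rod-like cells. It was subtracted in an alternative, not in the values reported.

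The ratios and lists were tested on simulated data, Poisson counts drawn from the pooled profile of a class at the measured depths. These draws follow the counting model of the intervals and hold no variation between cells. The rates below therefore show recovery under counting error alone. The interval lay on the right side of 1 for 76.1%, 95.5% and 100% of genes set to a 1.5-, 2- or 4-fold difference in amacrine-like cells, and for 14.9%, 22.4% and 54.5% in endothelial-like cells. The alternatives covered the mitochondrial limit, the gene minimum, doublets, depth, scaling, weighting of cells, free RNA and the level minimum. Added after the data were seen were shares outside the immune classes, naming of the OPTC-led cluster by its markers, and medians over amacrine clusters. A scaling on the median ratio of all genes would shift values by 0.17 log2 in rod-, 0.12 in bipolar- and 0.10 in endothelial-like cells. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with random seed 1.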

Results

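Single-cell RNA sequencing counted transcripts in retina from 2 macaques, 1 after 6 h of ligation of the ophthalmic artery, the vessel that supplies the eye, and 1 after a sham operation. The ischemic library held 5857 barcodes with 14673493 UMIs, and the sham library 5265 barcodes with 12287948 UMIs. After filtering, 5311 ischemic and 4582 sham cells were kept, with a median of 1958 and 1653 UMIs per cell. Both groups consist of 1 library, so there are no replicates and every difference below is a difference between 2 libraries. The 95% intervals cover counting error only. The comparison asks which cell classes and which genes differ between ischemic and sham-operated retina.

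Immune classes made up 53.8% of the cells of the ischemic and 10.6% of the sham library, while rod-like cells were the largest class of the sham library and scarce in the ischemic one. Microglia-like cells, with markers that brain and retinal microglia share with macrophages, made up 48.5% of ischemic cells (47.2% to 49.9%, 2578 cells) and 8.93% of sham cells (8.12% to 9.79%, 409 cells), a 5.44-fold higher share (4.90 to 6.05). Rod-like cells, the photoreceptors of dim light, made up 2.5% of ischemic cells (2.10% to 2.96%, 133 cells) and 40.5% of sham cells (39.1% to 41.9%, 1855 cells), a 16.2-fold lower share (13.6 to 19.4). Amacrine-like cells, inhibitory interneurons of the inner retina, held 30.7% against 14.8%, which is 2.08-fold higher (1.90 to 2.28). Cells with neutrophil or monocyte markers held 4.44% against 1.05%, 4.24-fold higher (3.10 to 5.91). T- or NK-like cells held 0.828% against 0.633%, with an interval of the ratio from 0.801 to 2.17.

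Lower shares in the ischemic library were measured for Müller-like glia (2.09-fold, 1.84 to 2.37), bipolar-like cells (4.02-fold, 3.07 to 5.31), cone-like cells (4.15-fold, 2.15 to 8.65), endothelial-like cells (3.08-fold, 2.30 to 4.17) and pericyte-like cells (16.0-fold, 6.53 to 50.8). Cells with markers of the retinal pigment epithelium, the layer behind the photoreceptors, were found 101 times in the sham library (2.20%) and 0 times among 5311 ischemic cells, which at the floor of 3 counts allows a share of up to 0.0565%. Ganglion-like cells, whose axons form the optic nerve, held 1.47% and 1.35%, a difference within counting error (ratio 1.09, 0.768 to 1.54). The value for cone-like cells rests on 12 ischemic cells and depends on the mitochondrial limit: the log2 ratio of cone shares was -2.05, but 1.21 with at most 10% and -4.91 with at most 50% mitochondrial UMIs. These shares add up to a whole. Among cells outside the immune classes, Müller-like cells made up 15.3% of the ischemic and 16.5% of the sham library, rod-like cells 5.42% and 45.3%, amacrine-like cells 66.6% and 16.6%, and ganglion-like cells 3.18% and 1.51%.

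Microglia-, Müller- and endothelial-like cells lay in different clusters in the 2 libraries, and rod-like cells in part. Ischemic microglia-like cells filled clusters 2, 3, 4, 22 and 31. HAMP, CD163, C1QC and CCL2 were each among the leading genes of several of these, and TNF of cluster 3. Of the 409 sham cells, 406 lay in cluster 9, whose leading genes included CCL8, GPR34, P2RY12, CCL2 and C3. CCL2 was thus a leading gene on both sides, and P2RY12 also counted as a marker of clusters 2, 3, 4 and 31. Ischemic Müller-like cells lay in cluster 11, led by GFAP, CHI3L1 and SERPINA3, and sham cells in clusters 12 and 13. Ischemic endothelial-like cells formed cluster 29 and sham cells cluster 15. Of the rod-like cells, cluster 1 held 15 ischemic and 1315 sham cells, cluster 5 held 62 and 531, and cluster 28 held 56 and 9. Depth differed by class: the median UMIs per cell were 2377.5 against 1164 in microglia-like cells and 1537 against 2142 in rod-like cells. The least UMIs of a deposited barcode were 501 and 500. Of the kept cells, 13.6% of the ischemic and 29.9% of the sham library lay under 1000 UMIs. With at most 10% mitochondrial UMIs the log2 ratio of microglia shares was 4.90 in place of 2.44 and the log2 ratio of amacrine shares 3.87 in place of 1.06. The latter rests on 214 ischemic and 9 sham cells. Clusters closest to amacrine markers, of 154 ischemic and 29 sham cells and of 20 and 17, stayed unnamed at that limit and are not counted in it. With cells thinned to 1000 UMIs the log2 ratio of rod shares was -4.62 in place of -4.01.

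**Figure D1:**
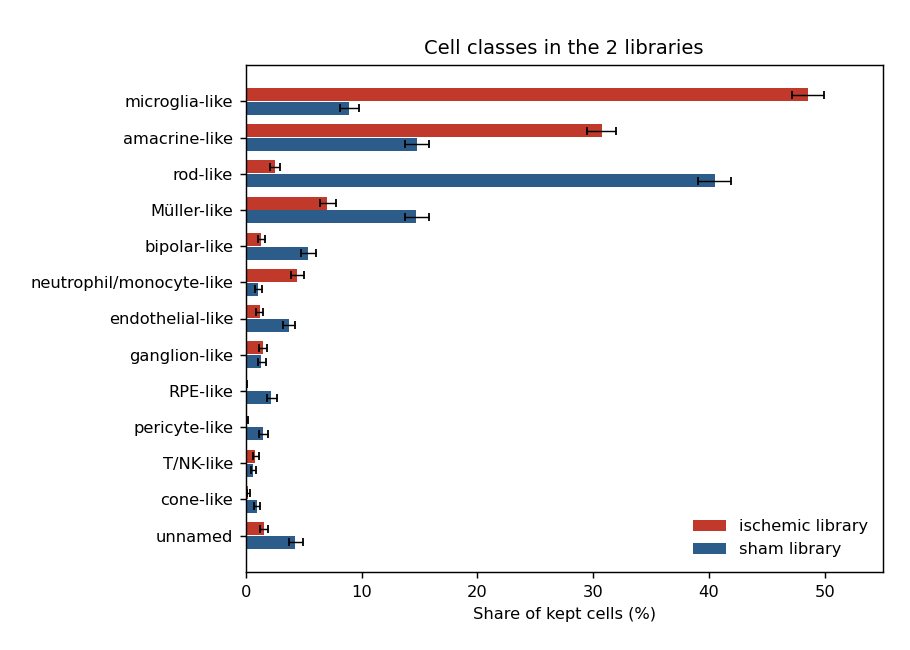
Share of kept cells (%) in each cell class for the ischemic (5311 cells) and sham (4582 cells) libraries, with bars for the shares and error bars for Clopper-Pearson 95% intervals. Microglia-like cells reach 48.5% in the ischemic library against 8.93% in the sham library, and rod-like cells 2.5% against 40.5%.

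In amacrine-like cells, genes of low oxygen, glucose breakdown, the unfolded protein and integrated stress response, early transcription and interferon signalling were higher in the ischemic library, while heat shock and cholesterol synthesis genes were lower. All 20 measured hypoxia targets were higher, with a median log2 ratio of 0.85 (0.64 to 0.97, percentile 100). STC2, a secreted glycoprotein of the stress response, was 11.6-fold higher (6.35 to 23.5), the transcription factor gene BHLHE40 10.1-fold (7.99 to 13.1), the vessel growth factor gene VEGFA 3.04-fold (2.46 to 3.79) and the mitophagy gene BNIP3 1.87-fold (1.74 to 2.02). ADM, the vasodilator adrenomedullin, was 10.5-fold higher (4.66 to 29.1), at a level under 10% of that in the highest class. Of 24 glycolysis genes 23 were higher (median 0.50, 0.39 to 0.66, percentile 99.99). Among them, PFKFB3, an activator of glycolysis, was 3.39-fold (1.78 to 7.13), the aldolase gene ALDOA 2.63-fold (2.41 to 2.87) and the pyruvate kinase gene PKM 2.47-fold higher (2.32 to 2.63).

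Of 21 genes of the unfolded protein and integrated stress response, 16 were higher in ischemic amacrine-like cells (median 0.99, 0.86 to 1.15, percentile 100). PHGDH and PSAT1, both enzymes of serine synthesis, were 14.1-fold (6.35 to 39.2) and 5.14-fold higher (2.83 to 10.3), and SESN2, a stress-induced regulator of growth signalling, 7.50-fold (3.67 to 17.8). Among the 5 lower members, chosen after their values were seen, were the chaperone genes of the endoplasmic reticulum CALR (1.97-fold lower, 1.81 to 2.15) and HSP90B1 (1.36-fold lower, 1.26 to 1.48). The immediate early genes were higher for 17 of 18 members (median 1.76, 1.58 to 2.0, percentile 100; 1.79 with zeros at their bound). NPAS4, a neuronal activity gene, had 70 UMIs in the ischemic and 0 in the sham class, at least 13.2-fold higher. FOS was 8.44-fold (6.32 to 11.5) and BTG2 5.74-fold higher (2.65 to 14.8), both at under 10% of their level in the highest class. With free RNA subtracted the median of the immediate early genes was 0.83. All 8 interferon response genes were higher (median 2.70, 2.44 to 3.07, percentile 100). IRF9, a transcription factor that carries the interferon signal, was 24.8-fold (12.5 to 58.0), IFIT3 15.7-fold (10.4 to 24.6) and BST2, an antiviral membrane protein, 9.90-fold higher (5.26 to 21.0).

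Lower in ischemic amacrine-like cells were 13 of 17 heat shock genes (median -0.39, -0.53 to -0.30, percentile 0.08). HSPA8, the constitutive cytosolic chaperone, stood at 318 CPM against 1413 CPM, 4.44-fold lower (4.1 to 4.81). HSPA4L was 2.58-fold (1.64 to 4.08) and HSPH1 2.41-fold lower (1.86 to 3.11). Of 14 cholesterol synthesis genes 12 were lower (median -0.54, -0.70 to -0.33, percentile 0.01), among them MSMO1 by a factor of 2.5 (2.11 to 2.96) and HMGCS1 by 2.26 (1.79 to 2.86). Nuclear genes of oxidative phosphorylation were lower for 37 of 48 members (median -0.25, -0.34 to -0.22, percentile 0), with NDUFA11 2.92-fold (2.5 to 3.41) and COX7C 1.96-fold lower (1.81 to 2.13). Synaptic genes split evenly, 14 higher and 13 lower, with a median of 0.00 (-0.10 to 0.07). Among the genes with the widest differences by rule were TAP1, a peptide transporter of antigen presentation (37.0-fold higher, 18.6 to 86.1), the cell cycle inhibitor gene CDKN1C (16.1-fold higher, 12.6 to 21.0) and IRF9. At the other end stood CARTPT, a neuropeptide precursor (8.43-fold lower, 7.47 to 9.55), and HSPA8. CARTPT was found in 4.96% of ischemic and 13.6% of sham cells of the class, with 16.1% and 13.7% of its UMIs in 1 cell. A shift among amacrine clusters was not tested for it. Rod markers took 0.202% of UMIs in ischemic and 0.915% in sham amacrine-like cells, a measure of the rod RNA in the medium. Microglia markers took 0.0307% and 0.00457%.

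In microglia-like cells the ischemic library was higher in hypoxia targets, glycolysis genes, genes of the unfolded protein and integrated stress response and inflammatory mediators, and lower in cholesterol synthesis genes. SPP1, the secreted phosphoprotein osteopontin, stood at 39748 CPM against 1478 CPM, 26.9-fold higher (25.1 to 28.9). HSPA5, the main chaperone of the endoplasmic reticulum, stood at 8723 CPM against 462 CPM, 18.9-fold higher (16.6 to 21.5). Of 18 hypoxia targets 17 were higher (median 1.68, 1.26 to 1.98, percentile 100; 1.74 with zeros at their bound). ADM was 52.3-fold (20.4 to 192), BNIP3 9.15-fold (4.96 to 19.1) and VEGFA 7.10-fold higher (4.13 to 13.4), and P4HA2, an enzyme of collagen maturation, at least 3.57-fold. Of 21 glycolysis genes 19 were higher (median 1.32, 1.00 to 1.77, percentile 100). The lactate dehydrogenase gene LDHA was 10.5-fold (7.61 to 14.8), the glucose transporter gene SLC2A3 8.39-fold (7.52 to 9.40), ALDOA 6.24-fold (4.63 to 8.60) and PKM 6.08-fold higher (5.11 to 7.28).

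Other stress and early genes of microglia-like cells went both ways. Of 19 members of the unfolded protein and integrated stress response 15 were higher (median 0.83, 0.54 to 1.02, percentile 99.94), with ATF5 7.17-fold (2.77 to 26.5), PPP1R15A 4.34-fold (3.74 to 5.08) and HERPUD1 2.90-fold (2.58 to 3.27) beside HSPA5. Heat shock genes were higher for 11 of 15 members (median 0.53, 0.36 to 0.98, percentile 99.4), among them BAG3 6.07-fold (3.18 to 13.3), HSPA6 3.95-fold (1.67 to 12.3), DNAJB1 3.53-fold (3.0 to 4.19) and DNAJA1 2.69-fold (1.86 to 4.03). The immediate early genes had 9 members higher and 18 lower (median -0.19, -0.25 to -0.12), with DUSP2 7.49-fold (4.27 to 14.5), KLF10 4.39-fold (3.24 to 6.11) and NR4A3 3.30-fold higher (2.30 to 4.91). Lower members, chosen after their values were seen, included MYC (2.51-fold lower, 1.73 to 3.56) and FOS (2.06-fold lower, 1.99 to 2.13). Nuclear genes of oxidative phosphorylation had a median near 0 (-0.06, -0.10 to 0.08).

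Of 25 inflammatory mediators 19 were higher in ischemic microglia-like cells (median 1.58, 1.41 to 1.80, percentile 100). The cytokine gene IL6 was 26.6-fold (10.4 to 97.7), the chemokine gene CXCL10 12.5-fold (6.30 to 28.9), IL1B 9.90-fold (7.04 to 14.4) and CCL5 5.66-fold higher (4.63 to 6.98). Others differed little or were lower: CCL2 had a ratio of 1.04 (0.974 to 1.11), TNF was 1.11-fold (1.02 to 1.21) and the prostaglandin synthase gene PTGS2 4.91-fold lower (3.64 to 6.55). Of 11 interferon response genes 10 were higher (median 1.44, 1.10 to 1.81, percentile 100), with IFI27 19.8-fold (14.5 to 27.9), IRF9 3.71-fold (2.0 to 7.79) and IFI6 3.31-fold (2.78 to 3.96). IFIT3 was 5.27-fold higher (2.54 to 13.2), at under 10% of its level in the highest class. The microglial activation list mixes genes of activated microglia with homeostatic ones such as CX3CR1 and P2RY12, so its median does not measure activation. The list had 8 members higher and 8 lower (median 0.06, -0.03 to 0.16). In it SPP1 was higher, while GPNMB, a lysosomal glycoprotein, was 23.1-fold (17.6 to 30.6), the fractalkine receptor gene CX3CR1 7.86-fold (5.69 to 10.8) and the purine receptor gene P2RY12 6.49-fold lower (5.77 to 7.29). Of 16 cholesterol synthesis genes 13 were lower (median -1.69, -1.94 to -1.43, percentile 0), among them MSMO1 7.59-fold (5.42 to 10.5), FDPS 6.26-fold (4.81 to 8.10) and FDFT1 4.89-fold (3.57 to 6.64).

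The genes with the widest differences in microglia-like cells by rule were G0S2, an inhibitor of fat breakdown (63.6-fold higher, 46.1 to 90.3), the decoy interleukin-1 receptor gene IL1R2 (at least 46.3-fold, with 0 sham UMIs) and the interleukin-2 receptor gene IL2RA (ratio 142, 25.5 to 5621, from 1 sham UMI). Lowest were the lipid mediator enzymes LTC4S (50.1-fold lower, 37.5 to 67.8) and HPGDS (43.4-fold, 27 to 72.2) and the phospholipase D family gene PLD4 (42.3-fold, 26.3 to 70.5). These values set cells of different clusters against each other. With at most 10% mitochondrial UMIs, which left 28 sham microglia-like cells, the median was 0.97 for hypoxia targets and 0.34 for the unfolded protein and integrated stress response. Among members above 100 CPM it was 1.98 for glycolysis and 1.23 for heat shock genes.

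Müller-like glia of the ischemic library carried high levels of reactivity and interferon genes and low levels of homeostatic genes. GFAP, the intermediate filament protein of reactive glia, was 89.7-fold higher (64.0 to 130). Of 21 glial reactivity genes 18 were higher (median 2.84, 1.81 to 3.07, percentile 100), among them the chitinase-like genes CHI3L1 (65.6-fold, 46.7 to 95) and CHI3L2 (42.0-fold, 16.0 to 157), the protease inhibitor gene SERPINA3 (18.2-fold, 14.3 to 23.6) and CP, which encodes the copper carrier ceruloplasmin (8.36-fold, 7.63 to 9.17). A single sham cell held 64.7% of the sham UMIs of CHI3L1. VIM was 1.34-fold higher (1.25 to 1.43), and CRYAB 1.15-fold lower (1.06 to 1.24). All 13 interferon response genes were higher (median 3.44, 3.11 to 3.87, percentile 100), with BST2 23.7-fold (8.85 to 89.3) and IRF9 21.9-fold (10.3 to 55.7). The ratios of OAS1 (61.4, 10.5 to 2476) and IRF7 (24.0, 3.79 to 1001) rest on 1 sham UMI each.

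Hypoxia targets were higher for 17 of 19 members in ischemic Müller-like cells (median 0.88, 0.55 to 1.30, percentile 100; 0.90 with zeros at their bound), with BHLHE40 7.63-fold (6.0 to 9.82), VEGFA 5.41-fold (3.98 to 7.48) and ANGPTL4, a regulator of lipoprotein lipase, at least 6.67-fold higher. Immediate early genes were higher for 16 of 17 members (median 2.02, 1.57 to 2.15, percentile 100), with BTG2 13.8-fold (8.63 to 23.5) and the phosphatase gene DUSP1 10.3-fold (7.88 to 13.7). Inflammatory mediators had 9 of 11 members higher (median 2.09, 1.37 to 2.88, and 2.18 with zeros at their bound). CXCL10 was at least 43.1-fold and SOCS3, a brake on cytokine signalling, 7.74-fold higher (2.96 to 25.6). CCL3 and CXCL8 ranked between them by ratio. Free RNA of microglia-like cells may account for CCL3 and CXCL8 in amacrine-like cells, and this was not tested in Müller-like cells. Lower were 15 of 19 Müller homeostasis genes (median -0.85, -1.13 to -0.80, percentile 0). The retinoid carrier gene RLBP1 was 3.30-fold (3.06 to 3.56), the potassium channel genes KCNJ13 and KCNJ10 3.57-fold (2.63 to 4.93) and 3.28-fold (2.09 to 5.34), and the carbonic anhydrase gene CA2 3.34-fold lower (1.81 to 6.65). Genes of ion transport were lower for 11 of 14 members (median -0.49, -0.82 to -0.19, percentile 1.06). Of 78 ribosomal protein genes 76 were higher (median 0.62, 0.56 to 0.66, percentile 100), for example RPL9 2.26-fold (1.99 to 2.57). By rule the widest differences were those of CHI3L1, CXCL10 and the complement gene CFB (42.5-fold higher, 25.1 to 78.4), and of NNAT (23.2-fold lower, 8.85 to 86.6), AKR1C1 (8.73-fold lower, 6.88 to 11.2) and MYBPC1 (16.3-fold lower, 6.14 to 61.2). Free RNA was put at 7.85% of UMIs in the ischemic and 12.9% in the sham class, and microglia markers took 0.0295% and 0.00416%.

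**Figure D2:**
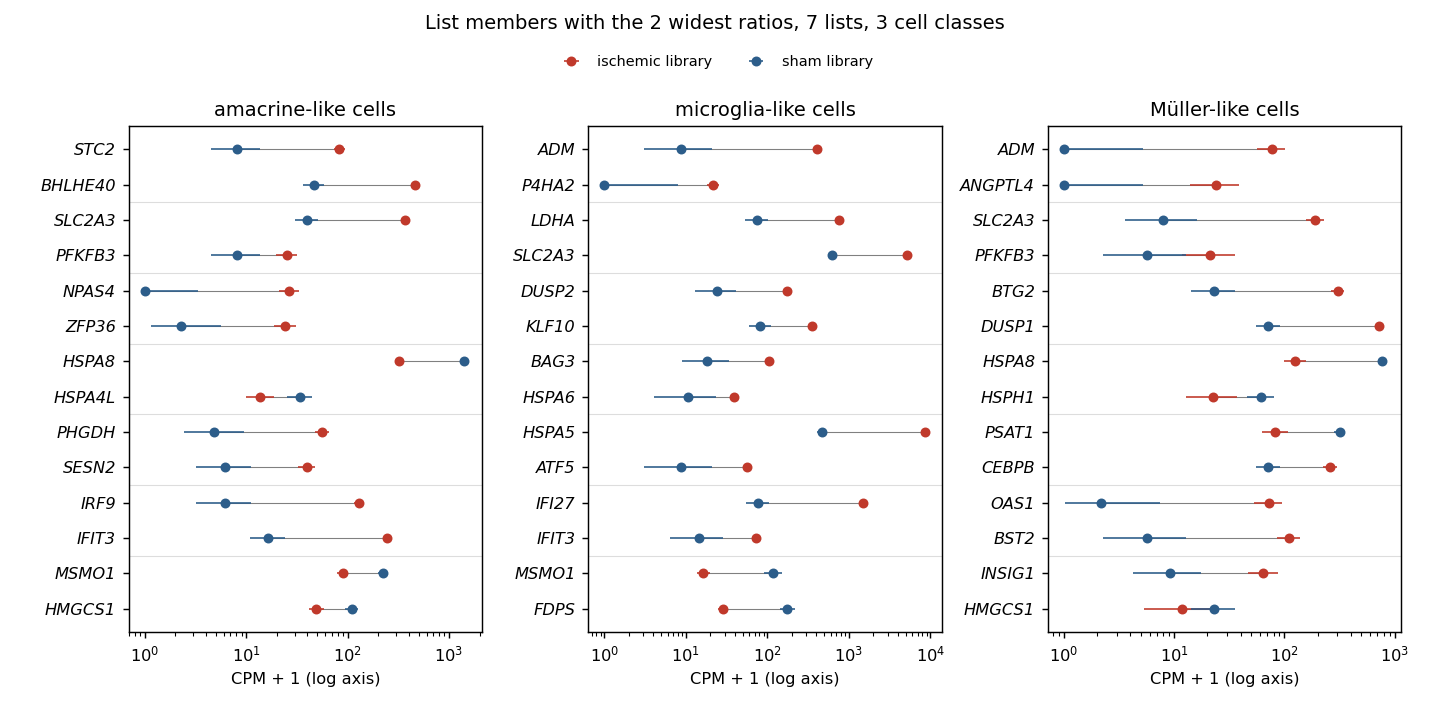
Level in CPM, plus 1, on a log axis, of the members with the widest ratio of 7 gene lists in amacrine-, microglia- and Müller-like cells, with points for the class sum of the ischemic (red) and sham (blue) library and bars for exact Poisson 95% intervals. In amacrine-like cells IFIT3 lies 15.7-fold higher in the ischemic library, and in microglia-like cells HSPA5 stands at 8723 against 462 CPM.

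Rod-like cells that were present in the ischemic library had lower levels of rod phototransduction genes than those of the sham library. Of 28 rod phototransduction genes 23 were lower (median -0.72, -0.81 to -0.64, percentile 0). The transcription factor gene NR2E3 was 3.29-fold (2.51 to 4.42) and the phosphodiesterase subunit gene PDE6G 4.69-fold lower (4.35 to 5.06), while GUCA1B and GRK1 were 3.25-fold (2.30 to 4.5) and 3.23-fold higher (2.10 to 4.79). Of 14 cell death genes 8 were higher (median 1.52, 0.53 to 1.92, percentile 99.9), with the pro-apoptotic genes BBC3 12.5-fold (3.73 to 37.9) and BAK1 9.25-fold higher (3.48 to 22.4); among members above 100 CPM that median was -0.0075. The 12 immediate early genes were all higher (median 2.44, 2.04 to 2.84), with KLF6 14.7-fold (8.95 to 23.8) and JUN 7.61-fold (4.25 to 13.1), both at under 10% of their level in the highest class. Microglia markers took 0.0387% of UMIs in ischemic and 0.0049% in sham rod-like cells, and higher with them were the 5 measured microglial activation genes (median 3.93, 2.31 to 5.17) and the 7 inflammatory mediators (median 4.62, 2.48 to 5.04). Hypoxia targets had 15 of 17 members higher, 5 of them with an interval above 1 (median 0.64, 0.31 to 1.00, percentile 85.7; 0.57 with zeros at their bound). Matched random lists in rod-like cells had a median of 0.37 for the hypoxia list and 0.52 for the immediate early list. For these lists 0 is therefore not the point of no difference. Mitochondrially encoded genes were lower for 12 of 13 members (median -0.72, -0.85 to -0.65, percentile 0.13), with ND2 2.55-fold lower (2.34 to 2.78). By rule the highest genes were the DNA damage gene GADD45A (16.3-fold, 11.3 to 23.3), ADSSL1 (17.1-fold, 9.41 to 30.8) and the protease inhibitor gene A2M (11-fold, 8.53 to 14.2). The lowest were PDE6G, SAMD7 (5.84-fold lower, 4.15 to 8.50) and CD59, a complement inhibitor (ratio 9.86 lower, 3.36 to 48.0, from 3 ischemic UMIs). The ischemic class held 133 cells, in part from other clusters than the sham class, and free RNA was put at 10.5% of its UMIs against 3.59% in sham rods.

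Bipolar-like cells, which relay photoreceptor signals, had higher hypoxia targets and lower heat shock genes in the ischemic library. Of 18 hypoxia targets 13 were higher, 5 of them with an interval above 1 (median 0.61, 0.33 to 1.06, percentile 99.2), with BHLHE40 3.12-fold (1.99 to 4.89) and INSIG2 4.02-fold (1.59 to 10.4). DDIT4, an inhibitor of growth signalling, had a ratio of 11.7 (2.23 to 116) from 2 sham UMIs. Heat shock genes were lower for 12 of 17 members, 4 of them beyond counting error (median -0.63, -0.99 to -0.07, percentile 0.15; -0.43 with zeros at their bound), with HSPA8 2.26-fold lower (1.66 to 3.15). The highest genes by rule were GADD45G (8.94-fold, 4.48 to 19.1), the phosducin gene PDC (5.05-fold, 4.04 to 6.33) and C15H9orf9 (ratio 18.4, 4.02 to 171, from 2 sham UMIs). PDC belongs to the rod phototransduction list and was also higher in ischemic amacrine-, microglia- and Müller-like cells. Free RNA was put at 7.36% of UMIs in ischemic and 7.68% in sham bipolar-like cells, and the source of PDC was not tested. The lowest were NEK2 (at least 8.45-fold lower), the calcium-binding protein gene CABP2 (at least 5.17-fold lower) and the glutamate receptor gene GRIK1 (8.50-fold lower, 3.83 to 23.5). The ischemic class held 71 cells, and with at most 10% mitochondrial UMIs the log2 ratio of C15H9orf9 was -1.10.

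Endothelial-like cells of the ischemic library were higher in hypoxia targets and inflammatory mediators. Of 21 hypoxia targets 19 were higher, 12 of them with an interval above 1 (median 2.26, 1.48 to 2.99, percentile 100; 1.44 with zeros at their bound). ADM was 40.7-fold (20.9 to 90.4), ANKRD37 38.6-fold (17.2 to 107) and HILPDA, a gene of lipid storage, 22.8-fold higher (9.20 to 72.8), and ANGPTL4 at least 6.10-fold. Of 22 inflammatory mediators 19 were higher, 13 of them with an interval above 1 (median 2.19, 1.76 to 2.98, percentile 100; 1.82 with zeros at their bound). The neutrophil attractant gene CXCL8 was 39.9-fold (19.8 to 94.0), PTGS2 25.9-fold (14.4 to 51.3), NFKBIA 6.28-fold (5.32 to 7.44) and the adhesion molecule gene ICAM1 4.24-fold higher (2.53 to 7.31). Heat shock genes were higher for 11 of 17 members, 3 of them with an interval above 1 (median 0.82, 0.08 to 1.15, percentile 99.7; 0.80 with zeros at their bound), with DNAJB1 5.57-fold (3.54 to 9.01) and HSPB1 2.55-fold (1.86 to 3.52). Interferon response genes had 9 members higher and 6 lower (median 0.23, -0.35 to 0.36), with IFIT2 5.08-fold higher (2.53 to 10.9). Among the highest genes by rule were CSF3, the granulocyte growth factor (ratio 463, 82.4 to 18386, from 1 sham UMI), and the superoxide dismutase gene SOD2 (46.8-fold, 28.4 to 82.7). The lowest were the transporter gene SLCO1A2 (at least 11.3-fold lower), IGFBP6 (ratio 30.7 lower, 8.33 to 257, from 2 ischemic UMIs) and SDPR, a caveolar protein gene (19.1-fold lower, 7.30 to 70.8). The ischemic class lay in cluster 29, with 64 ischemic cells and 1 sham cell, and the sham class in cluster 15, with 169 sham cells. Microglia markers took 0.729% of UMIs in ischemic and 0.477% in sham endothelial-like cells, where 8 of 9 microglial activation genes were higher (median 1.86, 1.02 to 3.15; 2.02 with zeros at their bound), and free RNA was put at 7.74% and 14.0%.

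Ganglion-like cells, the deepest class with a median of 11925.5 UMIs per ischemic and 10794 per sham cell, had the widest list median for the unfolded protein and integrated stress response among the 7 classes. Of 22 members 18 were higher (median 1.64, 1.43 to 2.0, percentile 100; 1.66 with zeros at their bound). DDIT3, the stress transcription factor CHOP, was 29.1-fold higher (20.1 to 43.6), SESN2 at least 23.0-fold and TRIB3, a pseudokinase gene that DDIT3 induces, at least 5.01-fold. PHGDH had a ratio of 107 (18.9 to 4252) from 1 sham UMI. Of 11 cell death genes 8 were higher (median 1.89, 1.45 to 2.31, percentile 100), with GADD45A 7.12-fold (5.15 to 10.1). CDKN1A, an inhibitor of the cell cycle, had a ratio of 19.0 (4.98 to 161) from 2 sham UMIs. Immediate early genes were higher for 7 of 8 members (median 2.06, 1.46 to 2.76; 2.14 with zeros at their bound), with ATF3, a gene induced by axon injury, at least 24.3-fold higher. All 8 interferon response genes were higher (median 3.07, 2.57 to 3.52, percentile 100), with IFIT3 28.3-fold (15.2 to 59.6) and IFIT1 12.3-fold (6.54 to 26.3). Hypoxia targets had 14 of 17 members higher (median 0.88, 0.59 to 1.24, percentile 99.99), with STC2 10.4-fold (5.51 to 22.3), DDIT4 10.3-fold (3.79 to 39.2) and BHLHE40 4.02-fold (2.95 to 5.58). Lower were 10 of 12 cholesterol synthesis genes (median -1.53, -1.72 to -1.15, percentile 0), with MSMO1 5.47-fold (3.49 to 8.93) and INSIG1 3.79-fold (1.98 to 7.74), and 11 of 17 heat shock genes (median -0.42, -0.66 to -0.16, percentile 0.19), with CHORDC1 4.17-fold (2.59 to 6.98), HSPA8 3.73-fold (3.38 to 4.13) and HSPB1 3.20-fold lower (2.23 to 4.67). The values rest on 78 ischemic and 62 sham cells with 22.2% and 23.0% mitochondrial UMIs, close to the limit of 25%. With at most 10% of them 5 sham cells were left, and with at most 50% the class held 228 ischemic and 183 sham cells (4.12% and 3.68% of the libraries).

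**Figure D3:**
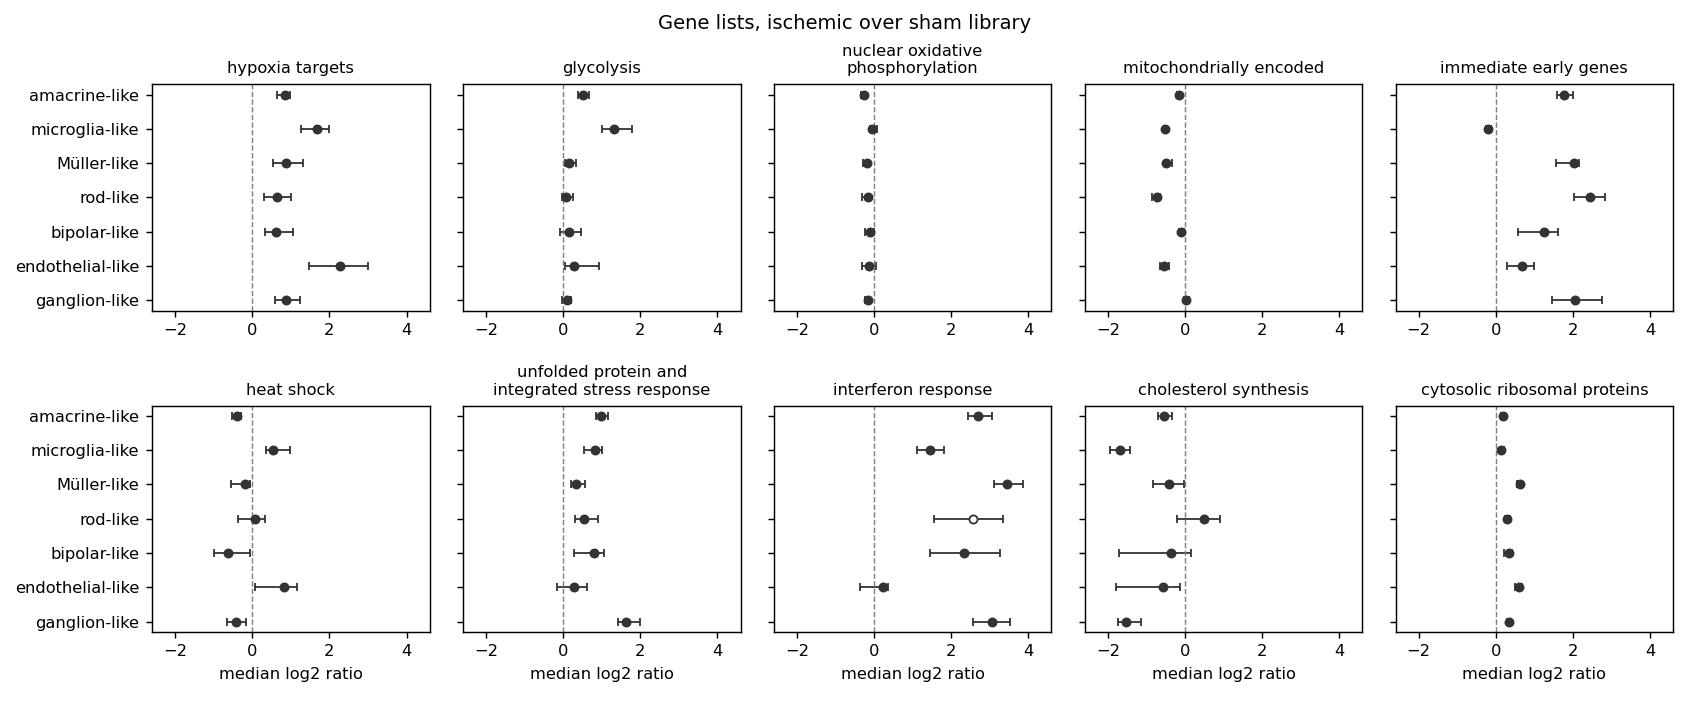
Median log2 ratio of level (ischemic over sham) of 10 gene lists in each of 7 cell classes, with points for the medians, bars for 95% intervals from 500 draws of the counts, and an open point where a list had under 5 members. Hypoxia targets lie above 0 in every class, from 0.61 in bipolar-like to 2.26 in endothelial-like cells. In rod-like cells their median of 0.64 stands at percentile 85.7 of matched random lists, which themselves have a median of 0.37. Heat shock genes lie above 0 in microglia-like (0.53) and endothelial-like cells (0.82). They lie below 0 in amacrine-like (-0.39), bipolar-like (-0.63) and ganglion-like cells (-0.42), with Müller-like (-0.20) and rod-like cells (0.08) between.

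The sham library alone gives the levels of metabolic genes across classes of an operated retina with its artery open. Glycolysis genes took 2.26% of UMIs in ganglion-like (2.23% to 2.30%), 1.23% in amacrine-like, 1.11% in Müller-like, 0.901% in rod-like and 0.389% in microglia-like cells (0.372% to 0.406%). Nuclear genes of oxidative phosphorylation took 3.38% in ganglion-like, 2.56% in rod-like and 1.08% in microglia-like cells, and mitochondrially encoded genes, under the limit of 25% per cell, 22.2% in ganglion-like and 3.55% in pigment epithelium-like cells. Ion transport genes took 1.14% in ganglion-like and 0.216% in microglia-like cells, and genes of glutamate and GABA handling 1.12% in Müller-like against 0.458% in amacrine-like cells. Immediate early genes took 4.43% in microglia-like (4.37% to 4.49%), 2.13% in endothelial-like and 0.019% in ganglion-like cells.

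Single genes of these lists in the sham library, chosen after their values were seen, split by class. SLC2A1, the glucose transporter of barrier cells, stood at 4289 CPM in endothelial-like (3979 to 4616) and 2792 CPM in pigment epithelium-like cells, and the related SLC2A3 at 614 CPM in microglia-like cells (548 to 685). ENO1 stood at 5445 CPM in Müller-like (5291 to 5603) and 1115 CPM in ganglion-like cells, where the neuronal enolase gene ENO2 reached 2094 CPM. CKB, the brain creatine kinase, stood at 6301 CPM in rod-like (6218 to 6384) and 8735 CPM in cone-like cells. ATP1B1, a gene of ion transport, stood at 3656 CPM in ganglion-like cells.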

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

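The tests of dilution, of broken rods, of the loss of the outer retina, of the loss of other cells, of blood cells and of interferon UMIs summed within clusters were chosen only after the results they measure had been seen.

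Heat shock genes lay on opposite sides of 0 in different classes, and the difference between classes was not tested. Their median log2 ratio was 0.53 in microglia-like (percentile 99.4) and 0.82 in endothelial-like cells (percentile 99.7), where 3 of 11 higher members had an interval above 1. It was -0.39 in amacrine-like (percentile 0.08), -0.63 in bipolar-like (percentile 0.15, with 4 of 12 lower members clear of counting error) and -0.42 in ganglion-like cells (percentile 0.19), and lay between in Müller-like (-0.20, percentile 18.7) and rod-like cells (0.08, percentile 27.8). Single members did not all follow their list: DNAJB1, a chaperone partner of HSP70, was 1.59-fold higher in amacrine-like cells (1.24 to 2.05), at under 10% of its level in the highest class, and HSPA8 was 1.31-fold lower in endothelial-like cells (0.842 to 2.08), within counting error.

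Rod-like cells held 2.5% of the ischemic and 40.5% of the sham library. Dilution by immune cells cannot be the whole cause, since outside the immune classes the log2 ratio of rod shares was still -3.06 (-3.33 to -2.81). Rods broken in the suspension would leave rod RNA behind. Rod markers in amacrine-like cells had a median log2 ratio of -1.79 (-1.90 to -1.66). Breakage in suspensions that began with like numbers of rods would give 0 or more, but those numbers are not known. Rod RNA also fell less than the rod shares outside the immune classes (-3.06), so the comparison cannot exclude broken rods. A tissue piece that lacked the outer retina as a whole cannot be told apart. The log2 ratio of cone shares exceeded that of rod shares by 1.96 (0.86 to 2.95) on 12 ischemic cones. At up to 50% mitochondrial UMIs it lay below that of rod shares (difference -0.94, -2.43 to 0.25). In every other setting that named the cells again the difference was above 0 with its interval, from 1.47 to 4.65 (the latter at up to 10%). Cells with pigment epithelium markers, from the layer behind the photoreceptors, numbered 0 in the ischemic and 101 in the sham library. They were not part of this comparison. The log2 ratio of rod shares itself was -3.44 at up to 10% and -3.97 at up to 50%, and a loss of rods after ligation, a loss during dissociation and a different retinal region stay open, none of them tested.

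Microglia-like cells held 48.5% against 8.93%. A loss of other cells that spared amacrine-like cells would lift microglia- and amacrine-like cells by the same factor. The log2 ratio for microglia-like cells exceeded that for amacrine-like cells by 1.39 (1.19 to 1.59). At up to 10% mitochondrial UMIs the excess was 1.02 (-0.27 to 2.17), where few sham cells of both classes were left. Clusters closest to amacrine markers, of 154 ischemic and 29 sham cells and of 20 and 17, stayed unnamed there. A loss that also took amacrine-like cells could give such an excess. The comparison therefore cannot exclude a loss of other cells. Blood left in the vessels is a candidate source of part of these cells that stays open. The log2 ratio for neutrophil- or monocyte-like cells exceeded that for T- or NK-like cells by 1.70 (0.82 to 2.56). The interval of this excess does not exclude the limit of 1. The hemoglobin gene HBB, described under the other observations, stood higher in ischemic amacrine-, rod- and bipolar-like cells. It was not part of this comparison and was not tested as a measure of blood. Markers do not separate resident microglia from macrophages that entered the tissue, and a biological gain after ligation was not tested apart from the animal.

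Interferon and inflammatory genes were higher in ischemic amacrine-like cells, where free RNA of the many microglia-like cells could supply them. From 10 microglial markers this free RNA came to a median of 1.15% of the microglial level (0.984% to 3.61%), and interferon response genes stood at a median of 134 times the level it would give, or 42.5 times with the highest marker, which excludes it for the list as a set but not for IFI27 (5.97 and 1.90 times). Inflammatory mediators stood at a median of 1.76 times that level, so free RNA may account for CXCL8, CCL2 and CCL3, at 0.925 to 1.05 times, but not for IRF1, at 14.6 times (4.64 with the highest marker). A shift among amacrine clusters is excluded as the whole cause for the interferon list: UMIs of its 8 members were 1.55- to 7.79-fold higher within 7 clusters, with an interval above 1 in 6 and not in cluster 24 (0.974 to 2.48), and the list median was 2.16 when each gene was taken at its median over the clusters. A difference between the 2 animals that the ligation did not make cannot be told apart from the ligation for the median of 2.70 (2.44 to 3.07), because animal and group are one split.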

How the results depend on the processing

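Shares outside the immune classes, the naming of the OPTC-led cluster and the medians over amacrine clusters were chosen only after the results had been seen. Each value below is a log2 ratio; the cause was not tested. Depth limits the small classes: simulated 2-fold differences gave an interval clear of 1 for 22.4% of genes in endothelial-like cells. No paired analysis was possible because each library comes from another animal. Over all alternatives, the shares of 11 classes stayed within their counting interval 92 times, moved out of it 23 times and reversed 1 time. Medians of the 6 main lists in amacrine- and microglia-like cells stayed 96 times and moved 24 times, and other lists stayed 1196 times, moved 152 times and reversed 17 times. Named genes stayed 266 times, moved 21 times and reversed 1 time. Without the genes that differ most between libraries in the clustering, bipolar-like cells received no name, and other classes kept 93.2% to 99.7% of their cells.

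With at most 10% mitochondrial UMIs, shares gave 4.90 for microglia, 3.87 for amacrine, -3.44 for rod, -1.35 for Müller, -1.33 for bipolar, 3.81 for ganglion and 1.21 for cone (reversed, on 15 ischemic and 4 sham cells). In microglia the medians were 0.97 for hypoxia targets, 0.13 for oxidative phosphorylation and 0.23 for mitochondrially encoded genes (reversed). They were -0.44 for immediate early genes and 0.34 for the unfolded protein and integrated stress response. Mitochondrially encoded genes in bipolar (0.17) and C15H9orf9 (-1.10) reversed. It left 9 sham amacrine-like cells and so no amacrine medians, while clusters closest to amacrine markers with 29 and 17 sham cells stayed unnamed. With at most 50%, cone shares gave -4.91, oxidative phosphorylation in amacrine gave -0.21, and mitochondrially encoded genes in bipolar (0.11) and Müller homeostasis in ganglion (0.0012) reversed.

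With at least 500 genes, shares gave 2.70 for microglia, 0.87 for amacrine, -4.61 for rod and 1.52 for T or NK cells. Thinned to 1000 UMIs they gave 2.75, 0.67 and -4.62, and -1.02 for endothelial. Outside the immune classes they gave 2.01 for amacrine, -3.06 for rod, -0.11 for Müller, -1.05 for bipolar, -0.67 for endothelial, 1.07 for ganglion and -1.10 for cone. With no doublets removed, cone shares gave -0.89, immediate early genes gave 1.55 in amacrine and -0.25 in microglia, and Müller homeostasis in rod reversed (-0.77). Without mitochondrial and ribosomal genes in the total, microglia gave -0.14 for oxidative phosphorylation and -0.27 for immediate early genes. Cells weighted equally gave 1.57 for immediate early genes in amacrine. The median over amacrine clusters gave 0.79 for the unfolded protein and integrated stress response.

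With free RNA subtracted, amacrine gave 0.83 for immediate early genes and 0.70 for the unfolded protein and integrated stress response. Microglia gave 2.01 for glycolysis, 0.17 for oxidative phosphorylation, -0.29 for immediate early and 1.00 for heat shock genes. Reversed were Müller homeostasis in microglia (0.73), synaptic release (0.58) and microglial activation (-0.48) in Müller, and immediate early (-0.11), inflammatory (-1.86), rod phototransduction (0.49) and microglial activation genes (-2.00) in bipolar.

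With no minimum level, immediate early genes in amacrine gave 1.33, and glycolysis and heat shock in microglia 0.98 and 0.32. Glutamate and GABA handling in Müller (0.14) and cone phototransduction in rod (0.0064) reversed. At 100 CPM, amacrine gave 0.37 for glycolysis and 2.03 for immediate early genes, and microglia 1.98 for glycolysis and 1.23 for heat shock. Reversed were Müller homeostasis in microglia (0.72), synaptic release in Müller (0.041) and cell death in rod (-0.0075).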

Other observations

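HBB and FKBP5 below were chosen only after their values had been seen, and no test belongs to them. Endothelial-like cells differed in vessel genes: 10 of 17 members of the vascular list were higher in the ischemic library (median log2 ratio 1.02, -0.23 to 1.58, percentile 99.2; 0.44 with zeros at their bound). PLVAP, a protein of leaky capillaries, had a ratio of 35.6 (9.14 to 305) and the adhesion molecule gene SELE one of 25.4 (6.34 to 221), each from 2 sham UMIs. The chemokine gene CXCL12 was 10.8-fold lower (5.92 to 21.9). In amacrine-like cells, genes of glutamate and GABA handling were lower for 10 of 14 members (median -0.36, -0.46 to -0.09, percentile 0.3), with the transporter gene SLC6A11 3.57-fold lower (2.48 to 5.20), while GAD1, which makes GABA, was 1.60-fold higher (1.49 to 1.71). Clusters with glycinergic markers held 52.1% of ischemic (49.6% to 54.5%) and 45.1% of sham amacrine-like cells (41.3% to 49.0%). Cell death genes were higher for 10 of 13 members in amacrine-like cells (median 0.91, 0.47 to 1.12), with GADD45G 3.87-fold higher (2.95 to 5.15), and evenly split in microglia-like cells (median -0.03).

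FKBP5, a glucocorticoid target, stood above the free RNA limit in 4 of the 7 compared classes and was higher in the ischemic library in each. Classes under that limit are not given here, whatever their direction. FKBP5 was 27.7-fold higher in Müller-like (10.4 to 104), 9.06-fold in microglia-like (6.93 to 12.1), 5.54-fold in endothelial-like (2.70 to 12.3) and 3.55-fold in rod-like cells (2.15 to 5.61). It stood at 616 against 86.2 CPM in T- or NK-like and at 427 against 131 CPM in neutrophil- or monocyte-like cells. HBB, a hemoglobin chain of red blood cells, stood at 20550 CPM in ischemic and 1.13 CPM in sham rod-like cells, where 1 cell held 32.2% of the ischemic UMIs. In bipolar-like cells it stood at 8290 against 3.58 CPM, with 71.8% in 1 cell, and in amacrine-like cells at 889 against 2.58 CPM. Cluster 17, unnamed and led by OPTC, SFRP2, CHI3L1 and CFB, held 80 ischemic and 70 sham cells, and the unnamed cluster 21, with rod and bipolar markers, 2 and 127. Autophagy genes had a median of 0.03 in amacrine-like and 0.07 in microglia-like cells, and oxidative stress genes of -0.19 (-0.36 to 0.03) and 0.12.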
